A study of Mus musculus with 6 samples.

How the data were processed

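Bulk RNA sequencing had been performed on epithelial cells sorted from the mammary glands of wild-type C57BL/6 mice aged 6 to 8 weeks. Glands had been digested with collagenase and trypsin, and single cells had been stained and sorted by flow cytometry. Luminal cells had been taken as CD24-high and CD29-low and basal cells as CD24-low and CD29-high. Antibodies to CD45 (leukocytes), CD31 (endothelial cells) and CD140a (fibroblasts) shared one dye, per the labels, and the stain also held anti-EpCAM and the dead-cell dye DAPI. There were 4 luminal libraries and 2 basal libraries. The sample labels name 3 mice and the shared protocol names 4 mice for each experiment, and no label says whether replicate libraries came from separate animals. The p-values therefore measure only the spread between these 6 libraries, which may be partly technical.

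The deposited values are RPKM (read counts scaled to gene length and to the library's total), which the authors computed for each library without pooling. Per the submitters' processing notes, STAR 2.7.1a, featureCounts, Subread 2.0.0 and edgeR had been used with the mouse builds GRCm38 and mm10. The gene annotation, the counting options and the step in which each tool was used are not given in the sources used here. Groups were taken from the labels of each sample. A second deposited table was not used because one of its column names matched no label.

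The table held 50482 gene symbols, of which 30979 were above 0 in some library. Symbols were matched to single genes of the GENCODE M21 annotation of GRCm38, and 47521 (94.1%) matched. That annotation gave coordinates, exonic lengths and the exonic bases that each gene shares with any other gene on either strand (bedtools 2.31.1). Depth was estimated from the low values. The product of RPKM and exonic length fell on whole multiples of 1 step per library, within a tolerance of 0.02, for 91.7% to 93.1% of low values. The steps correspond to 70.9, 71.8, 73.7 and 74.1 M reads counted in luminal 1 to 4, and to 72.2 and 75.4 M in basal 1 and 2. At that depth 1 read in a gene of 1 kilobase equals 0.0133 to 0.0141 RPKM, far below the filter used here. These reads are estimates that depend on the annotation, and no count model was run on them as the main test. Of low values, 70.5% to 73.0% were even multiples of the step. Both reads of a pair may therefore often have been counted, and independent fragments may be fewer than these reads.

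Comparison of the libraries showed 2 sets that do not follow the sort. The sets were drawn from the share of genes lying almost wholly inside exons of other genes that reach 1 RPKM, cut at its largest gap. Set 1 held luminal 1, luminal 2 and basal 1, and set 2 held luminal 3, luminal 4 and basal 2. Of 771 genes that share at least 90% of their exonic bases with other genes and reach 1 RPKM in some library, 16, 17 and 17 reached 1 RPKM in the libraries of set 1, against 684, 688 and 691 in those of set 2. Both sets contain both cell types. Fold changes within each set are therefore given for some of the named genes, and an adjusted p within a set where it ends the call of a named gene. Trf, Tagln and Jund, which share 52.6% to 67.9% of their exonic bases with other genes, are reported as uncertain, as is Csf1r, whose values divide by set. No pair of libraries of one group agreed within sampling noise (mean chi-square per gene 44.7 to 224 on estimated reads divided by 2, as read pairs), so no 2 were merged as reads of one library. Repeat preparations of one pool of cells would also differ by more than that noise, so this does not show separate animals.

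Luminal and basal libraries were compared with limma 3.58.1 in R 4.3.3. Values were taken as log2(RPKM + 1), the model held the group only, variances were moderated with a trend on mean expression, and tests were two-sided. Genes with a mean RPKM of at least 1 in either group entered the fit. Benjamini-Hochberg adjusted p below 0.05 was the threshold, and counts with an absolute log2 fold change over 1 are also given. Fold changes are luminal minus basal on the log2(RPKM + 1) scale, which understates the change of genes with low values. Ratios of mean RPKM are given beside some of them, and those that rest on low basal values are marked.

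The comparison, the gene lists, the naming rule and most alternative settings were chosen before the data were examined. The test chosen for counts, edgeR's quasi-likelihood test, was not run because the values are RPKM. The fallback stated with it, limma, was used instead, and DESeq2 was not run either. Named genes are the 10 higher in each group with the largest absolute fold change among genes past the threshold. These also needed an average of at least 5 on the log2 scale of the fit, no overlap between the groups and no predicted or pseudogene name. The antigens of the sort, Runx1, Runx2, Runx3 and Cbfb were always named. So were up to 4 tested members of each list with the largest absolute fold change, and members of a lineage list that passed the test against its direction. This gave 112 genes, of which 110 were tested and 91 passed the threshold.

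There were 27 lists. They covered luminal, hormone-sensing, progenitor, milk, basal, contractile, stem cell, basement membrane, mesenchymal transition, Runx, Wnt, Notch, tight junction, growth factor receptor, cell cycle, immediate early, antigen presentation and lineage transcription factor genes. Markers of fibroblasts, endothelial cells, pericytes, myeloid cells, lymphocytes, adipocytes, Schwann cells, red cells and skeletal muscle completed them. Lists with at least 3 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The rotation test fry, which asks whether the members move one way on balance and does not compare them with other genes, was run beside it. Several lists share members. Pals1 and Ahsp matched no symbol in the table.

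Alternatives were a pseudocount of 0.1, no filter, a filter on estimated reads, median-of-ratios and upper-quartile scaling and limma-voom on estimated reads. Further ones were the replicate number as a block, each library left out in turn, equal group sizes, and a fit without mitochondrial, ribosomal protein and haemoglobin genes. Equal group sizes set luminal 1 and 2, both of set 1, against basal 1 of set 1 and basal 2 of set 2. Cell type is therefore partly confounded with library set there, and also where a single library is left out. Fits with library set as a term, within each set, on genes sharing no exonic base, and with scaling factors from those genes were added after the data had been seen. The procedure was tested on simulated reads with known changes in 50 genes for each fold and a single dispersion of 0.0257 for all genes. Far fewer genes were changed there than passed in these data, which makes the adjusted threshold stricter. The shares called in the simulation therefore do not carry over to these data. With a group-only model and no set difference, changes of 1.5, 2, 4 and 8-fold were called in 12.5%, 75.0%, 100% and 100% of changed genes, with 9 false calls among 149, over 14208 genes. With a set difference like that in these data, 0%, 2.04%, 50.0% and 68.0% were called, with 1 false call among 61, over 14659 genes. With library set as a term the same simulation gave 13.0%, 67.3%, 100% and 100%, with 12 false calls among 151. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.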

Results

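RNA abundance was measured in luminal and basal epithelial cells sorted from the mouse mammary gland, the inner milk-forming layer and the outer layer that holds the contractile myoepithelial cells. The series concerns an enhancer of Runx1 and luminal stem cells, and the libraries described here come from wild-type glands. The question put to them was which genes differ between the 4 luminal and the 2 basal libraries. The deposited values correspond to 70.9 to 75.4 M reads counted per library, so all 6 libraries were of similar depth.

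The libraries separated by cell type and by library set. Across the 8702 tested genes that share no exonic base with another gene, log2 values correlated at 0.955 to 0.986 between luminal libraries, at 0.967 between the 2 basal libraries and at 0.651 to 0.700 between luminal and basal libraries. Genes are not independent replicates, and these correlations are given as descriptions. The first principal component of those genes held 85.3% of the variance and parted luminal from basal. Over all 15399 tested genes, luminal 1 and luminal 3 correlated at 0.776 and basal 1 and basal 2 at 0.759. There the first component held 50.5% and parted luminal 1, luminal 2 and basal 1 (set 1) from luminal 3, luminal 4 and basal 2 (set 2). Genes sharing no exonic base differed between the sets by a median of 0.01 on the log2 scale, and genes sharing more than 90% by 3.65. The sets were drawn from genes of that last kind, so a large difference there was fixed in advance.

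**Figure D1:**
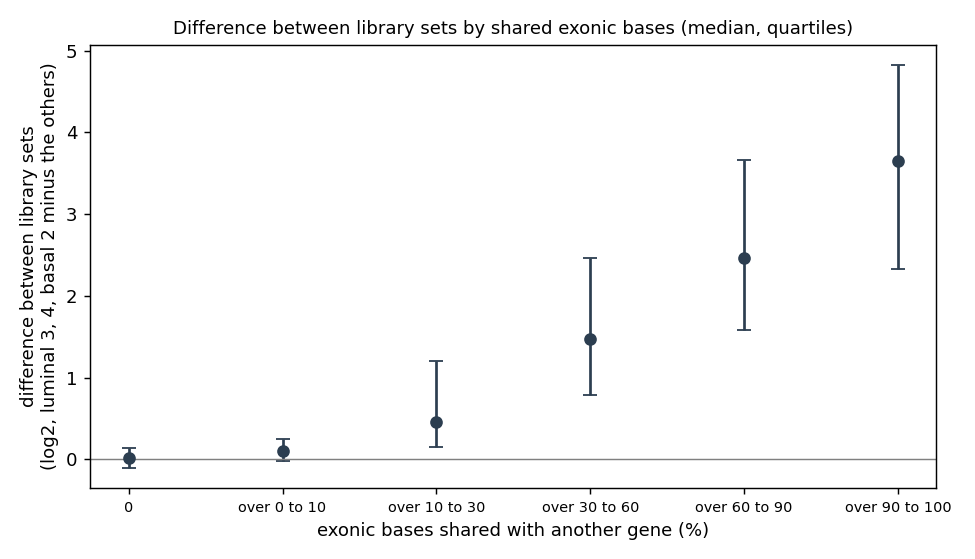
Difference between the library sets on the log2(RPKM + 1) scale (vertical axis, set 2 minus set 1) for genes grouped by the percentage of their exonic bases shared with another gene (horizontal axis); points are medians and bars span the quartiles. The median is 0.01 in the 8702 genes that share no base and 3.65 in the 672 genes that share more than 90%, the kind of gene from which the sets were drawn.

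Acta2, which encodes the smooth muscle actin of myoepithelial cells, and the basal keratin Krt14 were among the genes most strongly higher in basal cells. The antimicrobial genes Dmbt1 and Ltf, the secreted peroxidase Gpx3 and the water channel Aqp5 were among those most strongly higher in luminal cells. In all, 5386 of 15399 genes differed at an adjusted p below 0.05, with 2703 higher in luminal and 2683 higher in basal cells, and 6740 had an unadjusted p below 0.05. With a change over 2-fold as a further condition, 3358 genes remained, 1523 higher in luminal and 1835 higher in basal cells. Within set 1 alone 2242 genes passed, 732 of them higher in luminal cells. Within set 2 alone 6956 passed, 3889 of them higher in luminal cells. With library set as a term 6501 genes passed and 5353 of them were among the 5386. Among genes sharing no exonic base 4299 of 8702 passed, 2199 higher in luminal and 2100 higher in basal cells. No gene called in the pooled fit was called in the opposite direction by any of these fits. That could not differ with library set as a term or among genes sharing no exonic base, where each fold change equals that of the pooled fit. Within each set the same libraries are used again, so this is not separate support. Without basal 2, 3518 genes passed, 1466 of them higher in luminal cells, and without basal 1, 3923 passed, 1661 of them higher in luminal cells. Each of those fits, and each fit within a set, has a lone basal library, which is assumed to vary like the luminal ones. A fit within a set holds 3 libraries and leaves 1 residual degree of freedom, so a call lost there is not by itself a smaller difference.

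Acta2 (GRCm38 chromosome 19, 34241090 to 34255590) was at 3.54 ± 0.765 RPKM (SD, n = 4) in luminal and 5119 ± 558 (SD, n = 2) in basal libraries. Its log2 fold change was -10.15 (SE 0.17, adjusted p = 1.4e-05), with -9.85 within set 1 and -10.45 within set 2. Krt14 (chromosome 11, 100203162 to 100207548) was at 7.06 ± 2.47 RPKM in luminal and 1472 ± 42.5 in basal libraries, a log2 fold change of -7.57 (SE 0.30, adjusted p = 5.0e-05), with -7.86 within set 1 and -7.27 within set 2. Among genes with an average of at least 5 on the log2 scale, as the naming rule needed, the matricellular gene Ctgf followed at -5.96 and the apolipoprotein gene Apoe at -5.16. Genes below that average could change more, such as Myh11 at -8.82, given below. The collagen gene Col16a1 stood at -4.88, and the actin-binding genes Flna and Cotl1 at -4.52 and -4.45. Thbs1, Cnn2 and Lgals7 completed the 10 at -3.88, -3.82 and -3.66. Ctgf has no coordinates here because its symbol did not match the annotation. In the luminal direction Dmbt1 (chromosome 7, 131032053 to 131121630) was at 414 ± 193 RPKM in luminal and 1.73 ± 2.10 in basal libraries, a log2 fold change of 7.37 (SE 0.68, adjusted p = 7.2e-04), with 6.61 within set 1 and 8.13 within set 2. Ltf, which encodes lactoferrin, followed at 7.08, Gpx3 at 7.01 and Aqp5 at 6.94. The iodide transporter gene Slc5a5 stood at 6.74, the surface antigen gene Ly6d at 6.60 and the growth factor gene Areg at 6.53. Ido1, Prlr and Wfdc18 completed the 10 at 6.32, 6.25 and 6.14. Adjusted p-values of these 20 genes ran from 1.4e-05 (Acta2) to 0.0026 (Lgals7), and every luminal library lay on one side of both basal libraries, as the naming rule required.

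**Figure D2:**
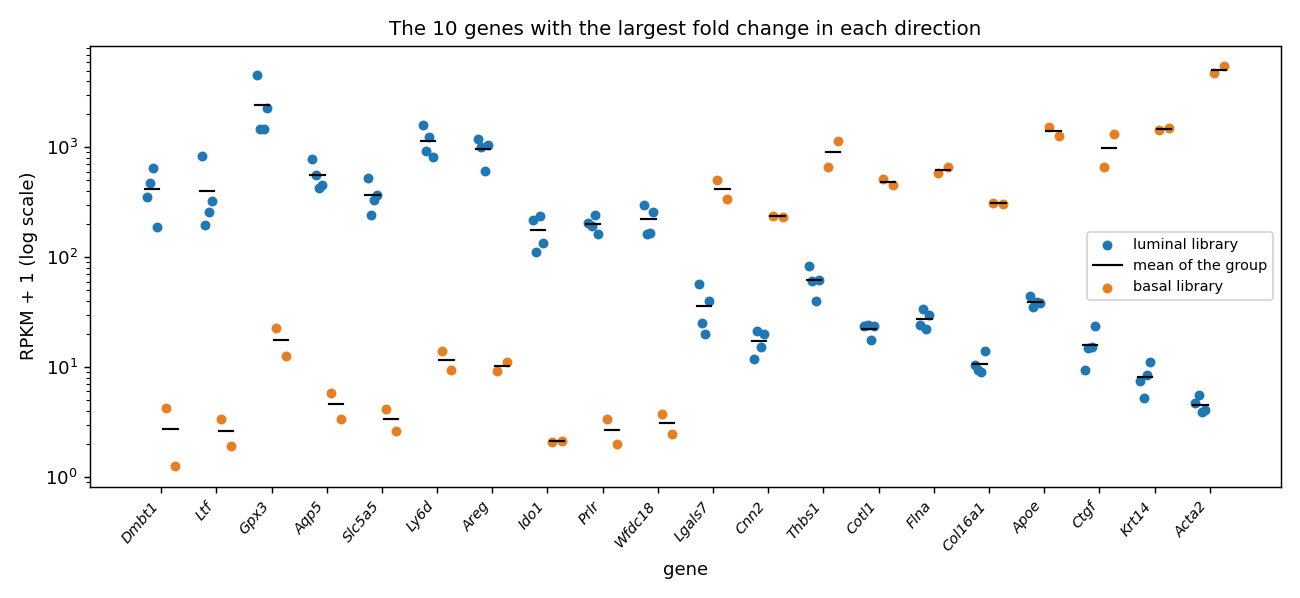
RPKM + 1 (vertical axis, log scale) of the 10 genes with the largest fold change in each direction under the naming rule (horizontal axis); points are the 4 luminal and 2 basal libraries and lines are group means. Acta2 lies at 2.86 to 4.55 RPKM in luminal and at 4724 and 5513 RPKM in basal libraries.

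Cd24a and Itgb1, which encode the antigens of the gates (CD24 and CD29), followed them. The sort itself favoured these directions. Cd24a and Epcam also stand among the luminal epithelial markers, and Itgb1 among the basal epithelial and basement membrane genes. The counts and tests of those lists given below include them. Cd24a was at 554 ± 87.9 RPKM in luminal libraries (SD, n = 4) and at 60.2 and 43.3 RPKM in the basal libraries, 10.7-fold higher in luminal cells (log2 fold change 3.40, SE 0.21, adjusted p = 1.7e-04). Epcam, an epithelial adhesion gene, was 9.23-fold higher in luminal cells (3.20, adjusted p = 1.4e-04). Itgb1 was 2.34-fold higher in basal cells, at 235 ± 32.6 against 100 ± 8.16 RPKM (log2 fold change -1.22, adjusted p = 0.0011). Its call did not hold with upper-quartile scaling (adjusted p = 0.079) or within set 1 alone (0.068, at a log2 fold change of -1.27). Pecam1, which encodes CD31, an antigen used to remove cells, was higher in basal cells, at 8.81 ± 0.166 against 1.03 ± 0.708 RPKM (-2.34, adjusted p = 0.0049, and 0.053 within set 1).

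Most tested luminal epithelial, tight junction, hormone-sensing and progenitor genes were higher in luminal cells. All 16 luminal epithelial markers were higher in luminal libraries (median log2 fold change 3.97; camera adjusted p = 4.2e-12, and adjusted p = 0.12 with an estimated correlation). The largest changes were in the claudin Cldn4 (649 ± 115 against 10.3 ± 1.82 RPKM; 5.83, with 5.86 and 5.81 within sets 1 and 2), the keratin Krt7 (5.67) and the claudins Cldn7 (5.60) and Cldn3 (5.50). Krt8 and Krt18, named after their values were seen, were 11.5-fold and 29.9-fold higher in luminal cells. Of 17 tight junction and apical polarity genes, 15 were higher in luminal cells and 2 did not pass (median 3.30; adjusted p = 9.7e-11, and 0.092 with an estimated correlation), and 3 of the 17 also stand in other lists. Cldn8 reached 44.4 ± 5.40 against 0.740 ± 0.267 RPKM (4.71). Counts adjusted over the list alone were the same for both lists.

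All 12 tested hormone-sensing genes were higher in luminal cells, both over all genes and adjusted over the list alone (median 4.48; adjusted p = 2.5e-08, and 0.049 with an estimated correlation). Areg, an EGF-family ligand, was at 964 ± 253 RPKM in luminal and 9.14 ± 1.35 in basal libraries (105-fold; log2 fold change 6.53, SE 0.30, adjusted p = 7.1e-05, with 6.90 and 6.17 within sets 1 and 2). The prolactin receptor gene Prlr was 118-fold higher, the pioneer factor gene Foxa1 89.3-fold higher (5.69) and the coregulator gene Cited1 80.1-fold higher (5.55). The ratios of Prlr, Foxa1 and Cited1 rest on low basal values, at 2.39, 1.88 and 3.52 RPKM in basal 1 and 1.01, 1.32 and 2.00 in basal 2. Cited1 varied among luminal libraries from 43.2 to 387 RPKM, and its call did not hold without basal 2 (adjusted p = 0.053) or within set 1 (0.12). Esr1 and Pgr, the estrogen and progesterone receptor genes, named after their values were seen, had log2 fold changes of 3.03 and 3.61.

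Of 13 tested luminal progenitor markers, 9 were higher in luminal and 1 in basal cells, also adjusted over the list alone (median 4.36; adjusted p = 5.2e-04, and 0.47 with an estimated correlation). Ltf (403 ± 290 against 1.63 ± 1.03 RPKM; 7.08), Wfdc18 (6.14), Plet1 (5.81) and the co-receptor gene Cd14 (5.68) had the largest changes. Itga2, which encodes the integrin CD49b, went against the list, at 5.11 ± 1.52 RPKM in luminal and 17.3 ± 2.26 in basal libraries (-1.61, adjusted p = 0.0068). That call did not hold without basal 2 (adjusted p = 0.062) or within set 1 (0.13). The 3 members that did not pass were Lcn2 (-0.20, adjusted p = 0.79), Mfge8 (0.45, 0.56) and Trf (0.86, 0.84). Trf shares 63.5% of its exonic bases with Gm20425 and its values are uncertain. Of 8 tested milk protein and milk fat genes, 6 were higher in luminal cells and 2 did not pass, and adjusted over the list alone 1 was higher in basal cells (median 1.78; adjusted p = 0.022, and 0.47 with an estimated correlation). The list did not pass without basal 2 (adjusted p = 0.053), within set 2 (0.061) or over genes sharing no exonic base (0.051). Both lists were highest in luminal 1, in 12 of 13 progenitor and 7 of 8 milk genes. Btn1a1, which encodes the milk fat globule protein butyrophilin, had a log2 fold change of 5.15 and the lactose synthase subunit gene Lalba of 4.57, and neither call held within set 1 (adjusted p = 0.052 and 0.068). The casein gene Csn3 was at 161 ± 86.5 against 7.43 ± 3.00 RPKM (4.18). Glycam1 was at 0.496 to 53.0 RPKM in luminal libraries and at 187 and 334 in basal libraries (-4.00, adjusted p = 0.098). Without luminal 1, which held the lowest of these values, it stood at -2.87 (adjusted p = 0.0099), and within set 2 at -3.62.

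Most tested basal epithelial, contractile and basement membrane genes were higher in basal cells. Of 17 basal epithelial markers 16 were higher in basal cells and 1 did not pass, and all 17 passed adjusted over the list alone (median -5.43; adjusted p = 2.3e-12, and 0.034 with an estimated correlation). With an estimated correlation this list and the hormone-sensing, contractile and basement membrane lists passed, and none of the 4 did when any single library was left out (adjusted p = 0.051 to 0.21) or with median-of-ratios scaling (0.088 to 0.12). Krt17 was at 1497 ± 48.0 RPKM in basal (SD, n = 2) and 3.06 ± 0.560 in luminal libraries (SD, n = 4; -8.54, SE 0.14, adjusted p = 1.4e-05, with -8.49 and -8.59 within sets 1 and 2). The matrix gene Sparc stood at -7.97 and Krt5 at -7.71. The member that did not pass, Sox10, was at 80.3 ± 27.7 RPKM in luminal and 141 ± 24.2 in basal libraries (-0.86, adjusted p = 0.10, and 0.025 without luminal 1).

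Of 16 tested myoepithelial contractile genes 15 were higher in basal cells, and all 16 passed adjusted over the list alone (median -5.51; adjusted p = 9.7e-14, and 0.049 with an estimated correlation). After Acta2, the smooth muscle myosin gene Myh11 was at 0.441 ± 0.109 against 652 ± 53.4 RPKM (-8.82), Myl9 at -8.72 and the calponin gene Cnn1 at -8.36. Tagln, which did not pass over all genes, was at 0.350 to 10.0 RPKM in luminal libraries, 22.2 in basal 1 and 1882 in basal 2 (-5.76, adjusted p = 0.076). It shares 67.9% of its exonic bases with Gm48529, and its level is uncertain. The pericyte markers Rgs5 and Pdgfrb were higher in the same libraries, at 6.69 and 4.85 RPKM in basal and 0.271 and 0.0882 in luminal libraries.

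Of 21 basement membrane and receptor genes 20 were higher in basal cells (median -3.82; adjusted p = 2.6e-14, and 0.038 with an estimated correlation), and adjusted over the list alone 1 was higher in luminal cells. Endothelial markers were higher in the same libraries, with Cdh5 at 9.67 RPKM in basal and 0.513 in luminal libraries. The collagen IV genes Col4a2 and Col4a1 changed by -7.17 and -7.02, the anchoring-fibril collagen gene Col7a1 by -6.50 and the laminin gene Lama1 by -6.02. Of 9 reported basal stem cell markers 7 were higher in basal cells and 2 did not pass, and 1 was higher in luminal cells adjusted over the list alone (median -2.28; adjusted p = 2.0e-04, and 0.094 with an estimated correlation). Id4 was at 159 ± 6.41 against 0.304 ± 0.115 RPKM (-6.94), the Notch ligand gene Dll1 stood at -5.19, the Wnt pathway gene Lgr5 at -3.39 and Gng11 at -2.52. Of 7 mesenchymal transition genes 5 were higher in basal cells and 2 did not pass, with 1 higher in luminal cells adjusted over the list alone (median -2.08; adjusted p = 0.010, and 0.28 with an estimated correlation). The list did not pass with luminal 1 and 2 set against both basal libraries (adjusted p = 0.064). Snai2 (-5.43), Vim (-5.25), Cdh2 (-2.41) and Fn1 (-2.08) had the largest changes, and Cdh2 and Fn1 were at 4.49 ± 1.26 and 5.18 ± 0.939 RPKM in basal libraries. Of the 6 tested fibroblast markers, a list that did not pass by camera, Dcn, Col1a2 and Col3a1 were higher in the same libraries, Dcn at 33.1 RPKM in basal and 1.13 in luminal libraries and Col3a1, whose call was lost in several fits given below, at 4.67 and 1.14. Col6a3 was higher in luminal libraries, at 9.07 against 0.648 RPKM, and Pdgfra and Col1a1 did not pass.

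Runx1, the transcription factor gene whose enhancer the series concerns, was at 22.8 ± 2.76 RPKM in luminal (SD, n = 4) and 25.6 ± 5.03 in basal libraries (SD, n = 2). The log2 fold change was -0.15 (SE 0.16, adjusted p = 0.55), with -0.34 within set 1 and 0.04 within set 2, and 0.04 without basal 1. No difference in Runx1 (chromosome 16, 92601466 to 92826149) was detectable against the spread between libraries. Runx2 was at 2.89 ± 1.52 in luminal and 5.22 ± 0.490 RPKM in basal libraries (-0.75, adjusted p = 0.18, and 0.024 without luminal 1). Their partner gene Cbfb was at 24.4 ± 5.73 and 22.1 ± 3.66 RPKM (0.12, adjusted p = 0.76), with -0.02 without luminal 2 and -0.04 without basal 2. Runx3 lay between 0.0106 and 0.0443 RPKM and was not tested. The corepressor gene Cbfa2t2 was higher in basal cells, at 7.18 ± 0.229 against 4.84 ± 0.246 RPKM (-0.49, adjusted p = 0.020). Its call did not hold without luminal 4 (adjusted p = 0.056), without basal 1 (0.15), without basal 2 (0.11), within set 1 (0.41), within set 2 (0.075) or with upper-quartile scaling (0.32). As a list, 1 of 4 tested Runx family and partner genes was higher in basal cells and 3 did not pass, also adjusted over the list alone (adjusted p = 0.34, fry 0.073).

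Of 30 lineage transcription factor genes, 15 were higher in luminal and 10 in basal cells, and 15 and 11 adjusted over the list alone (adjusted p = 0.44 against other genes). Of its 34 members 23 also stand in other lists. Id4, an inhibitor of basic helix-loop-helix factors, had a log2 fold change of -6.94, the p63 gene Trp63 of -5.72 (0.202 to 0.351 RPKM in luminal, 75.4 and 59.8 in basal libraries) and Snai2 of -5.43, and Foxa1 of 5.69. The median was 0.29 and the mean 0.27, in the luminal direction, while the rotation test pointed to basal cells (adjusted p = 0.0047). Among members sharing no exonic base the median was -0.87.

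Of 33 Wnt pathway genes, 22 were higher in basal and 4 in luminal cells, also adjusted over the list alone (median -1.98; adjusted p = 2.1e-06, and 0.25 with an estimated correlation). The secreted gene Dkk3 was at 87.3 ± 12.1 RPKM in basal and 1.11 ± 0.332 in luminal libraries (-5.40), the feedback inhibitor gene Nkd1 stood at -4.60 and the ligand gene Wnt6 at -4.51. The ligand gene Wnt4 went the other way, at 29.3 to 53.4 RPKM in luminal and 1.10 and 0.348 in basal libraries (4.48, adjusted p = 2.5e-04; 4.31 within set 1 and 4.65 within set 2). Of 15 Notch pathway genes, 7 were higher in basal and 3 in luminal cells, and 8 and 4 adjusted over the list alone (adjusted p = 0.19 against other genes, and 9.7e-06 by fry, toward basal cells). The ligand genes Jag2 (1.09 ± 0.394 against 128 ± 16.3 RPKM; -5.96) and Dll1 (-5.19) were higher in basal cells, and the receptor gene Notch3 (60.3 ± 5.43 against 3.69 ± 1.88 RPKM; 3.76) in luminal cells. The target gene Hey1 was higher in luminal cells (1.96, adjusted p = 0.022), and the call did not hold without luminal 4 (adjusted p = 0.050), without basal 1 (0.091), without basal 2 (0.13), within set 1 (0.14), with upper-quartile scaling (0.082) or with median-of-ratios scaling (0.051). Of 21 growth factor receptor genes, 6 were higher in luminal and 10 in basal cells, and 7 and 10 adjusted over the list alone (adjusted p = 0.31, and 0.015 by fry, toward basal cells). The oxytocin receptor gene Oxtr (7.88 ± 3.59 against 298 ± 18.1 RPKM; -5.16) and Tgfbr3 (-5.03) were higher in basal cells. Erbb3 (127 ± 15.5 against 4.94 ± 0.837 RPKM; 4.42) and Kit (4.36) were higher in luminal cells.

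**Figure D3:**
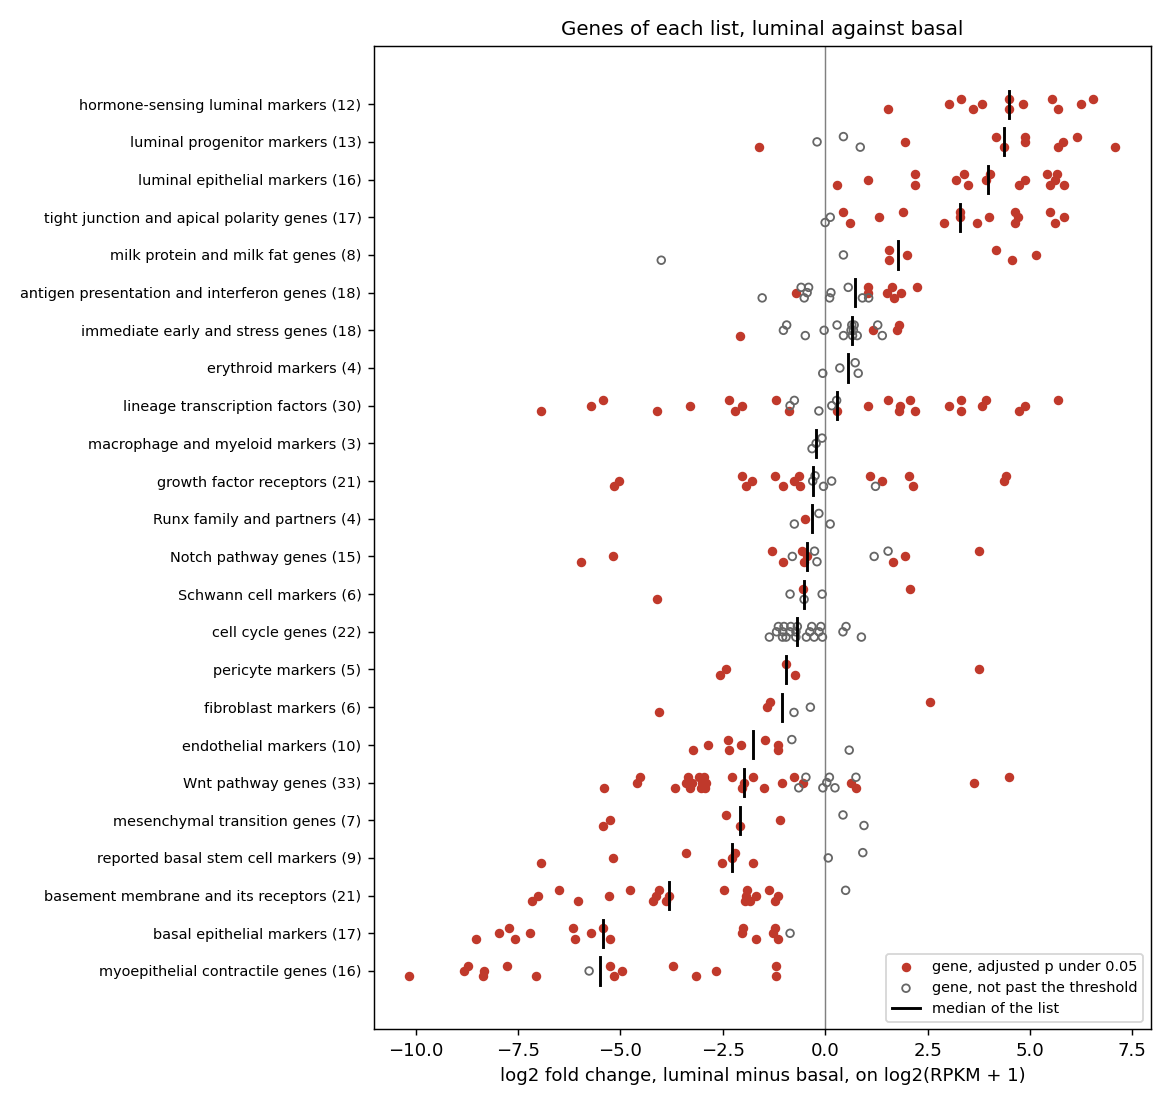
Log2 fold change on the log2(RPKM + 1) scale (horizontal axis, luminal minus basal) of the tested genes of each list (vertical axis, number tested in brackets); filled points passed the threshold, open points did not, and vertical lines are list medians. The medians run from -5.51 in contractile genes to 4.48 in hormone-sensing genes.

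None of the 22 cell cycle genes differed by limma over all genes or adjusted over the list alone (median -0.70, mean -0.52; camera adjusted p = 0.24, fry adjusted p = 0.54). The median was -0.15 without luminal 1 and -0.39 without basal 1, and -1.09 within set 1 and -0.23 within set 2. Without luminal 2 it was -1.05 and the list passed as lower in luminal cells (adjusted p = 0.021). Ccnb1 was at 3.37 ± 2.64 RPKM in luminal and 9.22 ± 3.83 in basal libraries (-1.36, adjusted p = 0.14, with 0.049 without luminal 2 and 0.029 within set 2), Ccna2 stood at -1.19 (0.25), Plk1 at -1.14 (0.23) and Mki67 at -1.04 (0.38). Without luminal 1 Ccna2 stood at -0.69, Plk1 at -0.75 and Mki67 at -0.47. Of 18 immediate early and stress genes 3 were higher in luminal and 1 in basal cells, and 1 and 1 adjusted over the list alone (adjusted p = 0.19, fry 0.12, with 0.0057 for luminal 1 and 2 against both basal libraries and 0.035 within set 1). The cytokine-signalling inhibitor gene Socs3 was at 855 ± 182 RPKM in basal and 201 ± 40.3 in luminal libraries (-2.09, adjusted p = 0.0017). Klf6 was higher in luminal cells (1.76, adjusted p = 0.011), without its call when basal 1 (0.051) or basal 2 (0.085) was left out or with upper-quartile scaling (0.085). Jund shares 52.6% of its exonic bases with Gm11175 and is uncertain (1.80, adjusted p = 0.047); its adjusted p rose to between 0.050 and 0.25 when luminal 1, luminal 3, luminal 4, basal 1 or basal 2 was left out, and to 0.075 without a filter on low values. Fosb was at 591 ± 315 and 204 ± 22.8 RPKM (1.40, adjusted p = 0.074), with 0.037 without luminal 1, 0.049 without luminal 4 and 0.020 with library set as a term. Of 18 antigen presentation and interferon genes 7 were higher in luminal and 1 in basal cells, also adjusted over the list alone (median 0.74; adjusted p = 0.16, and 0.044 by fry, toward luminal cells, with 0.043 without basal 1, 0.044 without a filter on low values and 0.048 for luminal 1 and 2 against both basal libraries). The immunoproteasome genes Psmb8 (25.4 ± 9.12 against 4.31 ± 0.345 RPKM; 2.24) and Psmb9 (1.86) led. Psmb8 lost its call without basal 1 (adjusted p = 0.051) or within set 1 (0.068), and Psmb9 without basal 1 (0.066), without basal 2 (0.074) or within set 1 (0.18). The MHC class I gene H2-K1 (1.67, with adjusted p = 0.071 within set 1), whose reads can be shared with related class I genes, and Bst2 (1.63, with adjusted p = 0.051 under upper-quartile scaling) followed.

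Several markers of cell types that the sort was set to remove were higher in the basal libraries. Within the gene lists the highest values were 35.8 RPKM for fibroblast, 17.5 for endothelial and 4.36 for myeloid markers. Of 10 endothelial markers 8 were higher in basal cells and 2 did not pass, and 9 passed adjusted over the list alone (median -1.75; adjusted p = 4.5e-04, and 0.39 with an estimated correlation). The claudin gene Cldn5 was at 0.490 ± 0.443 RPKM in luminal (SD, n = 4) and 13.2 ± 6.12 in basal libraries (SD, n = 2; -3.23), and the cadherin gene Cdh5 at 0.513 ± 0.469 and 9.67 ± 0.0432 RPKM (-2.87). Kdr stood at -2.38. Pecam1, given above, stood at -2.34. Of 5 pericyte markers 4 were higher in basal and 1 in luminal cells, also adjusted over the list alone (adjusted p = 0.063, 4.4e-04 by fry, toward basal cells, and 0.43 with an estimated correlation). The list passed without a filter on low values (adjusted p = 0.0015), with the filter on estimated reads (0.0088), with upper-quartile scaling (0.039), with limma-voom (0.024) and over genes sharing no exonic base (0.0058, median -1.70). Rgs5 (-2.58), Pdgfrb (-2.43) and Cspg4 (-0.96) were higher in basal cells, and Notch3, also in the Notch list, in luminal cells. Cspg4 lost its call with luminal 1 and 2 against both basal libraries (adjusted p = 0.19). Of 6 fibroblast markers 3 were higher in basal and 1 in luminal cells, also adjusted over the list alone (adjusted p = 0.17, and 0.030 by fry, toward basal cells). The proteoglycan gene Dcn was at 33.1 ± 3.87 RPKM in basal and 1.13 ± 0.676 in luminal libraries (-4.05), and the collagen gene Col6a3 at 9.07 ± 3.63 in luminal and 0.648 ± 0.0501 in basal libraries (2.55, with adjusted p = 0.061 within set 1). Col3a1 (-1.43, adjusted p = 0.023) lost its call without luminal 2 (0.053), luminal 3 (0.057), basal 1 (0.14) or basal 2 (0.064) and within set 1 (0.054) and set 2 (0.076), with upper-quartile scaling (0.083) and with a pseudocount of 0.1 (0.054), and Col1a2 (-1.36, adjusted p = 0.012) without basal 1 (0.061). Pdgfra, which encodes CD140a, was at 0.918 ± 0.376 and 1.44 ± 0.336 RPKM (-0.36, adjusted p = 0.27).

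Ptprc, which encodes CD45, reached at most 0.154 RPKM and was not tested. None of 3 tested myeloid markers differed by limma (adjusted p = 0.70 for the list, fry 0.46). Cd68 had a log2 fold change of -0.22, Lyz2 of -0.32, with 0.43 without basal 1, and Csf1r of -0.08. Csf1r shares 15.1% of its exonic bases with Hmgxb3 and stood at 2.23 to 2.42 RPKM in set 2 and at 0.0404 to 0.272 in set 1, so its values are uncertain. It had log2 fold changes of 0.22 without luminal 1, 0.15 without luminal 2 and 0.60 without basal 2. None of 4 erythroid genes passed by limma in the pooled fit (adjusted p = 0.49 for the list, fry 0.49), and Alas2 passed with library set as a term (adjusted p = 0.030). Hba-a1 (0.81, adjusted p = 0.59, and 0.042 without luminal 1), Alas2 (0.73, 0.063, with 0.018 without luminal 1 and 0.024 within set 2) and Hba-a2 (0.36, 0.70) were its largest, and Hbb-bs was at -0.06. Without basal 1 Hba-a2 was at -0.02, and Hbb-bs was at 0.34 without luminal 1 and 0.59 without basal 2. The alpha-globin genes are near-identical copies and their split is uncertain. Of 6 Schwann cell markers 1 was higher in luminal and 2 in basal cells, also adjusted over the list alone (adjusted p = 0.31, fry 0.36). Egr2 was at 93.3 ± 16.7 RPKM in basal and 4.73 ± 2.20 in luminal libraries (-4.11), and the myelin gene Mbp at 6.83 ± 0.325 in luminal and 0.883 ± 0.275 in basal libraries (2.06). Ncam1 (-0.54, adjusted p = 0.026) lost its call without luminal 3 (0.11) or luminal 4 (0.094), with upper-quartile scaling (0.082) and with a pseudocount of 0.1 (0.057). Of lymphocyte markers only Trac was tested, at 0.334 ± 0.0444 and 1.01 ± 0.307 RPKM (-0.58, adjusted p = 0.018), with 0.084 without luminal 3, 0.080 without luminal 4 and 0.073 with upper-quartile scaling. Of adipocyte markers only Fabp4 was tested, at 0.890 ± 0.823 and 14.7 ± 7.60 RPKM (-3.07, adjusted p = 0.0074), with 0.057 without basal 2 and 0.064 within set 1. Of skeletal muscle markers Acta1 (-0.88, adjusted p = 0.0097, and 0.063 within set 2) and Mylpf (0.64, adjusted p = 0.064) were tested. Mylpf had an adjusted p of 0.0080 without luminal 1, 0.029 with library set as a term and 0.020 within set 2.

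The 4 luminal libraries differed from each other in progenitor, milk and cell cycle genes. No label divides these libraries, and values are given without a test between them. Of 13 tested progenitor markers 12 were highest in luminal 1, as were 7 of 8 milk genes and 13 of 18 immediate early genes. Lalba was at 71.6 RPKM in luminal 1 and 12.8 to 19.5 in the others, Btn1a1 at 167 against 30.7 to 37.0, and Kit at 115 in luminal 1, 47.0 in luminal 2, 46.5 in luminal 3 and 61.7 in luminal 4. All 22 cell cycle genes were highest in luminal 2 and 21 were lowest in luminal 1, where Mki67 was at 1.91 RPKM against 16.7, 8.63 and 15.0 in luminal 2, 3 and 4. Of 12 hormone-sensing genes 6 were lowest and 3 highest in luminal 1, with Cited1 at 43.2 RPKM against 387, 258 and 196 and Areg highest there. Other lists also stood to one side in luminal 1. Of 16 luminal epithelial markers 11 were highest there, as were 5 of 6 fibroblast markers, and 7 of 10 endothelial markers were lowest. All 4 erythroid genes were lowest in luminal 1 and highest in luminal 2, with Hba-a1 at 0.243 RPKM against 9.43, 8.32 and 4.36 in luminal 2, 3 and 4.

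**Figure D4:**
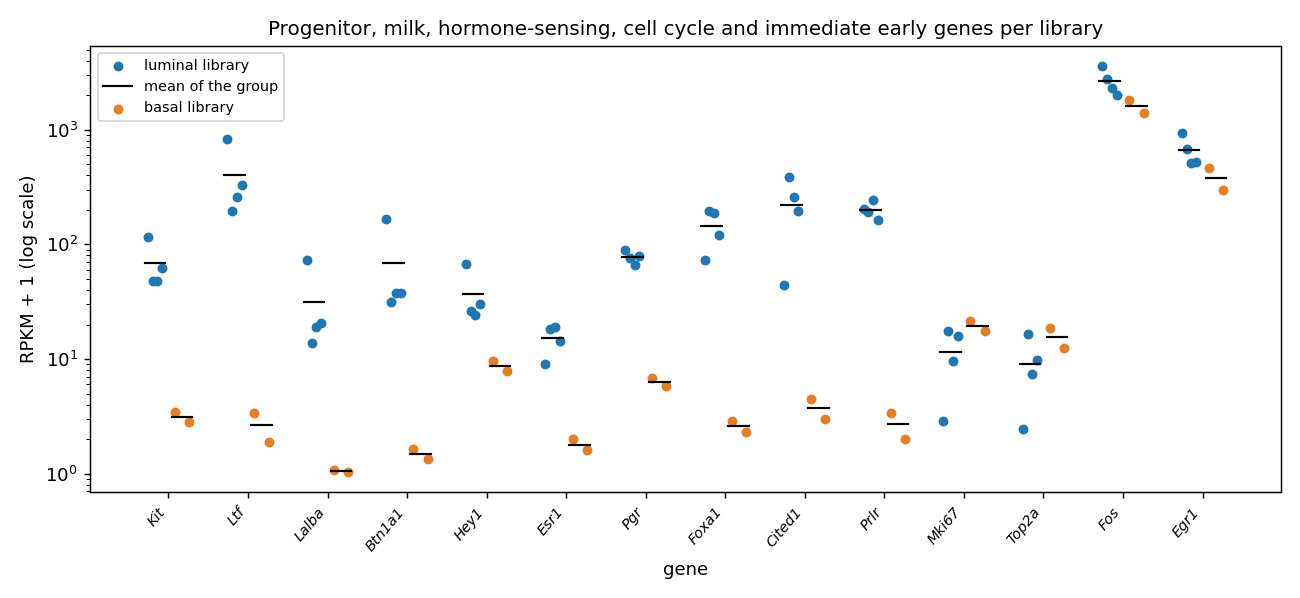
RPKM + 1 (vertical axis, log scale) of progenitor, milk, hormone-sensing, cell cycle and immediate early genes (horizontal axis); points are the 4 luminal and 2 basal libraries and lines are group means. Lalba reaches 71.6 RPKM in luminal 1 and at most 19.5 in the other luminal libraries, and Mki67 stands at 1.91 RPKM in luminal 1 and at 8.63 to 16.7 in the others.

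Of the 91 named genes that passed the threshold, 88 could be tested within both library sets, and all 88 had the same direction in both. They had been called from the same 6 libraries, so this agreement was close to fixed in advance and is not separate support. Leaving out some single library ended the call of 13 of the 91, set 1 alone ended 14 and set 2 alone 3, each named above with its value. Luminal 1 and 2 against both basal libraries ended 11, namely Cspg4, Cited1 (adjusted p = 0.061), Cbfa2t2 (0.12), Hey1 (0.064), Jund (0.18), Psmb9 (0.086), Col3a1 (0.065), Col1a2 (0.096), Trac (0.34), Ncam1 (0.38) and Acta1 (0.16). In that fit both luminal libraries are of set 1 and the basal libraries are of both sets, so the set difference is mixed into it. A call lost there is not by itself a smaller difference. Library set as a term ended none of the 91 and added Alas2, Fosb and Mylpf.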

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

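The tests on the counting of overlapping genes, on short RNAs in genes under 1 kb, on overlap as a source of the endothelial values and on luminal 1 were chosen only after the results they bear on had been seen. Those on short RNAs in longer genes, strand and a second endothelial list were written before their results were seen. Of 95 values compared among the 4 luminal libraries, 4 lay far from the other 3 by Dixon's gap test at its 95% critical value, and chance gives about 1 in 20, or 4.75. Cotl1 was at 16.5 RPKM in luminal 3 and at 22.5 to 23.2 in the others. Btn1a1 (167 RPKM), Lalba (71.6) and Hey1 (66.6) were high in luminal 1, against at most 37.0, 19.5 and 29.1 in the other luminal libraries.

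The values of luminal 1 were weighed with those of the progenitor, milk and cell cycle genes that also stood apart there. The difference in counting between the library sets was argued against, since luminal 1 and luminal 2 lie in the same set and a set difference cannot part them. In the 32 of these 41 genes that share no exonic base, luminal 1 stood apart by a median of 1.31 on the log2 scale (quartiles 0.96 to 1.63). These distances were signed in the direction already seen, so that median adds no separate support. Basal cells carried over into luminal 1 were also argued against, as 6 of 33 basal and contractile genes (18.2%) were highest in luminal 1. Fewer hormone-sensing cells in luminal 1 stay open, since 6 of 12 hormone-sensing genes (50.0%) were lowest there, which neither meets nor excludes the 80% set for that explanation. The labels give no difference between the luminal libraries, so no further biological explanation was tested.

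Genes lying almost wholly inside exons of other genes stood near 0 in luminal 1, luminal 2 and basal 1 and not in the other libraries. Short RNAs kept in set 2 were weighed as the whole cause. Of such genes, 139 of at least 1 kb still differed by a median of 3.25 on the log2 scale (quartiles 2.10 to 4.38), and 533 shorter ones by 3.76 (2.37 to 4.95). The median was 0.61 (0.14 to 1.11) in 457 short genes that share none. That smaller difference in short genes stays open. Strand-specific counting in set 1 was also weighed, and 391 genes nested on the same strand alone differed by a median of 3.75 (2.41 to 4.86). All these nested genes are of the kind from which the sets were drawn, so large medians in them were close to fixed in advance. They show that the pattern takes in longer genes and same-strand genes, which short RNAs alone or strand-specific counting alone would not give. They are not separate tests of those explanations. A candidate explanation is that reads overlapping several genes were left out in set 1 and counted in set 2. The median difference was 3.65 (2.33 to 4.83) in 672 nested genes, but the sets were drawn from genes of that kind, so a large difference there was fixed in advance. Genes not used to draw the sets differed by 1.48 at over 30% to 60% shared, by 2.46 at over 60% to 90% and by 0.01 where no base is shared. No biological explanation was tested because both sets hold both cell types.

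Endothelial markers were higher in the basal libraries although anti-CD31 was part of the sort. Reads shared with overlapping genes were argued against, as 8 of 9 list members sharing no exonic base (88.9%) were higher in both basal libraries than in every luminal one. Endothelial cells in the basal gate stay open: of a second list of 20 genes, none in another list, 18 were detected and 13 (72.2%) were higher in both basal libraries, between the bounds of 80% and 50% set in advance. The same held for 25.5% of all tested genes, and chance gives 6.67%. The most abundant of the second list by basal mean, Plvap, was at 38.4 RPKM in basal and 3.00 in luminal libraries, and Eng, at 13.3 and 22.5, went the other way. Ramp2 and Ly6c1 also fell short, and their values divide by library set, so the share is uncertain by these genes. Ramp2 was at 0.111 and 0.413 RPKM in luminal 1 and 2 and at 23.6 and 22.3 in luminal 3 and 4. Aqp1 and Ecscr fell short without such a division. Expression of these genes by basal epithelial cells themselves was not tested and also stays open.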

How the results depend on the processing

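Fits by library set, on genes sharing no exonic base and with scaling from those genes were chosen after the data had been seen. The count of 5386 genes was 3584 with upper-quartile scaling, 2781 with luminal 1 and 2 against both basal libraries, 2242 in set 1 alone and 3518 to 6454 when single libraries were left out (without basal 2 and without luminal 1). Genes higher in luminal cells (2703) numbered 1660, 1223, 732 and 1466 to 3613 in the same fits, and genes higher in basal cells (2683) numbered 1558 with equal groups and 1510 in set 1 alone. The count over 2-fold (3358) was 5372 with limma-voom, 3188 of them higher in basal cells, and 2104 in set 1 alone, 701 of them higher in luminal cells. All other settings except the replicate block kept these counts within 1.5 times. Smaller fits hold fewer libraries. With equal groups or a single library left out, the sets are also unbalanced between the cell types, so the set difference enters those counts. Upper-quartile factors divided by library set, at 0.731 to 0.883 in set 1 and 1.16 to 1.25 in set 2, against 0.884 to 1.07 from genes sharing no exonic base. That scaling therefore moves every gene between the sets, and a call lost under it is not by itself a smaller difference. How far this lowered the count was not tested, nor was the cause of the limma-voom count. With the replicate number as a block, 410 genes passed, 176 higher in luminal and 234 higher in basal cells, with the same counts over 2-fold; luminal 3 and 4 then add nothing to the comparison. Whether the numbers pair the libraries cannot be told from deviations from the group means, since the 2 basal libraries deviate as mirror images. These deviations correlated across genes at 0.787 between luminal 1 and basal 1 and at -0.883 between luminal 2 and basal 2, which follows the sets. Over genes sharing no exonic base the same correlations were 0.193 and -0.534. Of 24 lists, 12 passed with the preset correlation, 4 with an estimated one and 18 by fry. With an estimated correlation none of the 4 passed with median-of-ratios scaling (adjusted p = 0.0875 to 0.124), upper-quartile scaling (0.293 to 0.320), library set as a term (0.0880 to 0.0946) or any single library left out (0.0508 to 0.209). The myeloid list's median ran from -0.467 to -0.0303 when single libraries were left out, and its test pointed to luminal cells without basal 1. The transcription factor list had a median of -0.874 over genes sharing no exonic base, with or without library set as a term, and pointed to basal cells by fry (median 0.290). Genes that changed sign had not passed the threshold, and their ranges over left-out libraries were -0.348 to 0.0402 for Runx1, -0.0396 to 0.285 for Cbfb, -1.07 to 0.432 for Lyz2, -0.752 to 0.599 for Csf1r, -0.0176 to 0.734 for Hba-a2 and -0.705 to 0.588 for Hbb-bs. In set 2 alone Runx1 was at 0.0365, Lyz2 at 0.302 and Csf1r at 0.0340, and in set 1 alone Hbb-bs was at 0.315. The cause of these changes was not tested. Of 110 named genes, upper-quartile scaling ended 8 calls, equal groups 11, set 1 alone 14, the block 42 and library set as a term 0, while that term added 3. TMM, DESeq2 size factors, edgeR and DESeq2 were not run, since the values are RPKM, and library totals are already the scaling used. At 70.9 to 75.4 M reads, 1 read in a gene of 1 kilobase is 0.0133 to 0.0141 RPKM, and values near that level, such as those of Runx3, rest on few reads.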

Other observations

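The genes named in this part were chosen after their values were seen. Members of receptor families lay on opposite sides. Erbb2 and Erbb3 were higher in luminal cells, by 2.05 (SE 0.14, adjusted p = 2.5e-04) and 4.42 on the log2 scale, and Egfr was higher in basal cells, at 14.8 RPKM in basal and 3.02 in luminal libraries (-2.04, SE 0.33, adjusted p = 0.0063). The Egfr call did not hold in 4 of 21 other settings, and no setting turned its direction. Tgfbr1, which encodes a TGF-beta receptor, was at 22.7 RPKM in basal and 5.17 in luminal libraries (-1.94, adjusted p = 1.1e-04), while Tgfbr2 went the other way, at 34.0 in luminal and 15.2 in basal libraries (1.09, adjusted p = 0.022). The Tgfbr2 call did not hold in 8 of 21 other settings. Fgfr2 was higher in luminal cells (1.39, adjusted p = 0.0098) and Fgfr1 in basal cells (-0.61, adjusted p = 0.037), without their calls in 5 and 11 of 19 other settings. The Wnt ligand genes were also divided. Wnt7b was at 19.6 RPKM in luminal and 0.642 in basal libraries (3.63, adjusted p = 9.1e-05), and Wnt10a at 0.0305 in luminal and 12.2 in basal libraries (-3.67, adjusted p = 5.6e-05). Among other Wnt genes, the secreted inhibitor gene Sfrp1 stood at -3.34 and the transcription factor gene Tcf7 at -3.29. Of progenitor genes, the transcription factor gene Elf5 and the aldehyde dehydrogenase gene Aldh1a3 both stood at 4.88.

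Mitochondrially encoded genes took 0.934%, 1.28%, 1.28% and 0.997% of estimated reads in luminal 1 to 4, and 1.90% and 1.21% in basal 1 and 2. The 10 most abundant genes took 15.1% of all RPKM in luminal 1 and 9.22% to 11.1% in the other libraries. In a fit with cell type and library set, 2671 genes differed between the sets, 2612 of them higher in set 2 and 59 lower. Among genes sharing no exonic base, 227 of 8702 differed between the sets.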
